A study of Mus musculus with 4 samples.

How the data were processed

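RNA-seq libraries were made from hippocampal neurospheres of newborn mice, 2 of control and 2 of FGF13Aoe genotype, with cells of a mouse plated into 2 wells, per the labels' protocols. Total RNA was extracted with Trizol and libraries were prepared with a NEBNext Ultra kit, per the labels' protocols. The submitters' processing notes name STAR, DESeq2 and the mm10 genome build. Their versions, the gene annotation release and the use of strand in counting are not given in the sources used here.

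The authors deposited a table of 48178 genes with a normalized read signal for each library, that is, gene read counts divided by a size factor per library, together with their mean. It also holds the authors' log2 fold change, its standard error and a Wald score, and the authors' p-value and adjusted p-value. No per-library column was left out of use. In each library 100% of values were whole multiples of the smallest value above 0, within a tolerance of 1e-06 of the value. Dividing by that step gave reads per gene and the totals of 9724413 to 14092685 reads. The step of FGF13Aoe replicate 2, 1.012, was nearly as close to 1 as that of control replicate 1 but lay outside the limit used. In control replicate 1 the step was 0.991, close to 1, a case in which recovery of reads is not accepted. Count tests were therefore run on the other 3 libraries only. Count tests on all 4 libraries had been planned and run; they were withdrawn for this reason after their results had been seen, and are not reported. The read total, the replicate chi-square and ratios of genes with few reads still divide control replicate 1 by its step. The SD over genes of the difference between replicates was 0.43 log2 units in control and 0.59 in FGF13Aoe. Replicates differed by more than sampling noise (chi-square per degree of freedom 10.31 in control and 26.64 in FGF13Aoe), so none was taken for a repeated deposit.

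Groups and replicate numbers came from sample titles. Genes with a normalized count of at least 10 in at least 2 of the 4 libraries were tested, 15204 in all. FGF13Aoe was compared with control by limma 3.58.1 in R 4.3.3, with an intensity trend and without a replicate block, on log2(normalized count + 1). The test was two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are on this scale and understate the change of low genes. For a gene with 3 reads or fewer in a group the ratio of reads, scaled by the steps, is given with an exact 95% interval, which covers counting error only.

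The 40 gene lists were fixed from general knowledge before the data were examined. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and without an intensity trend, adjusted over 38 lists, and again with an estimated correlation and with fry. Named genes followed a rule fixed at the same time. It took Fgf13, then the 12 largest rises and 12 largest falls among called genes with a mean of at least 50 in the higher group, groups that did not overlap and a symbol that is not a predicted gene. It also took up to 4 members with the smallest p of each list described, with members needed for a count, the 4 most abundant called genes per direction, Neurod1 and Arid1b, and Xist and Ddx3y. Some genes that the rule took are not named in the text. Positions and exon overlaps came from GENCODE annotation of GRCm38, the assembly that mm10 names, which held 15191 of the 15204 tested genes; its release may differ from the authors'.

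Alternatives were another pseudocount, other filters, TMM scaling, median centring, no intensity trend, the authors' own p-values, a replicate block and leaving out each library. Tests by edgeR 4.0.16 and DESeq2 1.42.0 on reads of 3 libraries were added after the data were seen. The procedure was tested on simulated reads with the means, dispersions and depths of these libraries over 15126 genes. Limma recovered 44% of 100 genes changed 2-fold and 94% of 100 changed 4-fold, with 0 in the wrong direction. Of its calls in the simulation 10.24% were false, against the nominal 5%, so the counts of called genes may hold more false calls than the threshold states. Few genes were changed in the simulation, so the share may differ in these data. On 3 simulated libraries edgeR recovered 26% and 94% with 19.88% of calls false, and DESeq2 22% and 88% with 11.85% false. In a simulated list of 25 genes shifted 2-fold, camera gave p = 4.3e-27, camera with an estimated correlation 0.00684 and fry 0.00233. By each of them 0 of 20 unshifted lists had p under 0.05. Simulated genes were drawn independently, while estimated correlations in the real lists ran up to 0.864. The simulation therefore does not show how often camera at the preset correlation calls a list falsely in these data. Figures were drawn with matplotlib.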

Results

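In hippocampal neurosphere cultures carrying an FGF13A cassette, neuronal, synaptic, ion channel, DNA replication and mitochondrial respiration genes were lower than in control cultures. Oligodendrocyte, astrocyte, BMP target and ribosomal protein genes were higher. These were lists tested with a small preset correlation between genes, and none of them passed with an estimated correlation. By fry, which tests a list's own genes, the DNA replication, oligodendrocyte, BMP target and ribosomal protein lists did not pass either (adjusted p = 0.06001, 0.0709, 0.08096 and 0.1411). Syt1, the calcium sensor of synaptic vesicles, had a log2 change of -3.94 ± 0.16 (SE, n = 2 per group; adjusted p = 0.00111). Bcas1, expressed in newly forming oligodendrocytes, had a log2 change of 3.15 ± 0.22 (SE, n = 2 per group; adjusted p = 0.00121).

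RNA was sequenced from hippocampal neural progenitor cells of newborn C57BL/6 mice (postnatal day 0). The cells had been grown as neurospheres, floating clusters of progenitors and their progeny, in medium with 20 ng/ml FGF-2 and 20 ng/ml EGF, and were harvested on culture day 7. Per the labels, both groups carried hGFAPCre, a Cre recombinase under the human GFAP promoter, which is active in neural progenitors and astrocytes. Counts of Prm1, given below, leave open whether both groups carried or used the same transgene. The 2 control libraries had no FGF13A cassette at the ROSA26 locus, and the 2 FGF13Aoe libraries carried the cassette behind a loxP-flanked stop on 1 ROSA26 allele. FGF13 is an intracellular member of the fibroblast growth factor family that binds voltage-gated sodium channels and microtubules. The libraries held 11481591 and 14092685 gene-assigned reads in control replicates 1 and 2, and 9724413 and 11389767 reads in FGF13Aoe replicates 1 and 2. The labels do not say whether the replicates of a group came from separate pups, so p-values measure only the spread between these samples. In FGF13Aoe that spread may be technical. In control replicates 1 and 2 the Y-linked genes Ddx3y and Eif2s3y had 5 and 180 reads and 8 and 337 reads. The control libraries thus held unequal amounts of male RNA, and their spread is not only that of repeat libraries from the same cells.

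The first question was whether the FGF13Aoe cultures held more Fgf13 transcript. Fgf13 (ENSMUSG00000031137, GRCm38 chromosome X, 59062145 to 59568071) had normalized read counts of 772 and 769 in the control libraries and 5410 and 4447 in the FGF13Aoe libraries. Its log2 change was 2.67 ± 0.14 (SE, n = 2 per group; limma adjusted p = 0.00111), which is 6.36-fold. Counts per gene do not separate the cassette from the endogenous gene or the A isoform from others. Gt(ROSA)26Sor (ENSMUSG00000086429, chromosome 6, 113067428 to 113077333), the noncoding transcript of the locus that carries the cassette, rose from 68.4 and 70.0 to 1005 and 731 (log2 change 3.61 ± 0.21, adjusted p = 0.00111). Of its exonic bases 8.55% overlap Thumpd3 on the opposite strand, and it was chosen after its values were seen.

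The main comparison asked which transcripts differed between FGF13Aoe and control neurospheres. Of 15204 genes tested, 2467 were higher and 2906 lower in FGF13Aoe (limma adjusted p under 0.05), and 7307 had an unadjusted p under 0.05. A change of at least 2-fold was found in 1230 of the higher and 1765 of the lower genes, and a change of at least 8-fold in 68 and 332. Both libraries of a group lay beyond both of the other in 73.72% of tested genes, against 33.33% by chance. Log2 values correlated across genes at 0.984 between the control libraries, at 0.973 between the FGF13Aoe libraries and at 0.883 to 0.902 between groups; genes are not independent replicates. The authors' deposited table calls 2263 genes higher and 2711 lower, and 4666 genes were called there and here in the same direction and 0 in opposite directions. Without control replicate 1 the counts fell to 551 higher and 867 lower, and without control replicate 2 to 769 and 974. Of the genes chosen by the fixed naming rule, 58 lost their call without control replicate 1 and 54 without control replicate 2, against 8 and 9 without FGF13Aoe replicates 1 and 2.

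Large rises, among genes with a mean of at least 50 in the higher group and groups that did not overlap, were in Tead4, a transcription factor of the Hippo pathway, and in Tnn, which encodes the matrix protein tenascin-N. Tead4 counts were 3.96 and 1.63 in control and 232 and 83.0 in FGF13Aoe (log2 change 5.28 ± 0.62, adjusted p = 0.00354). Tnn counts were 10.9 and 12.2 against 597 and 272 (5.01 ± 0.41, adjusted p = 0.00163). Entpd2, Nfatc4, Lgi4 and Fxyd1 had log2 changes of 4.71 ± 0.33, 4.26 ± 0.48, 4.18 ± 0.46 and 4.15 ± 0.61. H2-K2, Bcl3, Papss2 and Bcas1os2 had log2 changes of 3.88 ± 0.45, 3.87 ± 1.01, 3.86 ± 0.42 and 3.86 ± 0.52. Counts in FGF13Aoe replicates 1 and 2 were 451 and 134 for Fxyd1 and 207 and 56.7 for Bcl3, against 141 and 144 for Bcas1os2. Adjusted p was at most 0.0321 in these genes, and Bcl3 lost its call without control replicate 1 (log2 change 2.53, adjusted p = 0.1014) and without FGF13Aoe replicate 1 (2.94, adjusted p = 0.1044). Values of Entpd2 and Lgi4 are uncertain because 28.8% and 44.9% of their exonic bases overlap Npdc1 and Fxyd3, those of H2-K2 because it resembles other histocompatibility genes, and those of Bcas1os2 because it lies antisense to Bcas1 and use of strand in counting is not stated.

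Within the same limits the largest log2 fall, on the scale of log2(count + 1), was in Prm1, a sperm chromatin protein gene (ENSMUSG00000022501, chromosome 16, 10796326 to 10805839). Its normalized counts were 1040 and 722 in the control libraries and 9.67 and 10.1 in the FGF13Aoe libraries (log2 change -6.32 ± 0.27, adjusted p = 0.00111). Gabra5, a GABA-A receptor subunit, fell from 502 and 327 to 8.46 and 6.07 (-5.63 ± 0.34, adjusted p = 0.00111). Cntnap5a, the muscarinic receptor gene Chrm3, the neurofilament gene Nefl, the transcription factor gene Bhlhe22 and Car10 had log2 changes of -5.14, -5.04, -5.02, -4.98 and -4.90. Nxph2, Fam198b, Mndal, Htr2a and Epha6 had 2 or 3 reads in the FGF13Aoe group, so ratios of control to FGF13Aoe are given with 95% counting intervals, which cover counting error only. The ratios were 69.7 (19.0 to 581) for Nxph2, 46.8 (15.7 to 229) for Fam198b, 51.1 (13.9 to 427) for Mndal, 47.0 (15.8 to 230.3) for Htr2a and 47.0 (15.8 to 230.3) for Epha6. Adjusted p was 0.0504 for Mndal without control replicate 1, where its log2 change was -4.23, and 0.0502 for Fam198b without control replicate 2, where its log2 change was -4.41. Of the exonic bases of Nefl 32.8% overlap Nefm on the opposite strand.

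Among abundant transcripts Gfap, an astrocyte intermediate filament gene, rose from 30384 and 12876 to 111437 and 135769 (log2 change 2.64 ± 0.45, adjusted p = 0.0095), and the lipid carrier gene Apoe from 22838 and 16406 to 93708 and 65711 (2.02 ± 0.31). Xist rose by 1.03 on the log2 scale. The abundant transcripts that fell were mt-Cytb (-1.10), mt-Nd1 (-1.63), mt-Nd2 (-2.05) and the tubulin gene Tuba1a (-0.83), of whose exonic bases 26.2% overlap a predicted gene. With 1 control library left, which is assumed to vary like the FGF13Aoe libraries, several of these calls ended. Without control replicate 1 adjusted p was 0.0586 for Apoe, 0.0802 for Xist, 0.2667 for mt-Cytb, 0.1397 for mt-Nd1, 0.0664 for mt-Nd2 and 0.2387 for Tuba1a, with log2 changes of 2.26, 1.33, -1.03, -1.70, -2.12 and -0.73. Without control replicate 2 it was 0.0979 for Gfap, 0.0966 for Apoe, 0.2691 for Xist, 0.22 for mt-Cytb, 0.1578 for mt-Nd1, 0.0686 for mt-Nd2 and 0.1599 for Tuba1a, with log2 changes of 2.02, 1.78, 0.72, -1.17, -1.56, -1.99 and -0.93. Without FGF13Aoe replicate 1 mt-Cytb did not pass (-0.74, adjusted p = 0.05095). Neurod1, a transcription factor of neuronal commitment, fell from 298 and 166 to 24.2 and 34.4 (-2.90 ± 0.37, adjusted p = 0.00441). Arid1b, a subunit of the BAF chromatin remodelling complex, had counts of 941 and 863 in control and 861 and 954 in FGF13Aoe (0.01 ± 0.12, adjusted p = 0.962).

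**Figure D1:**
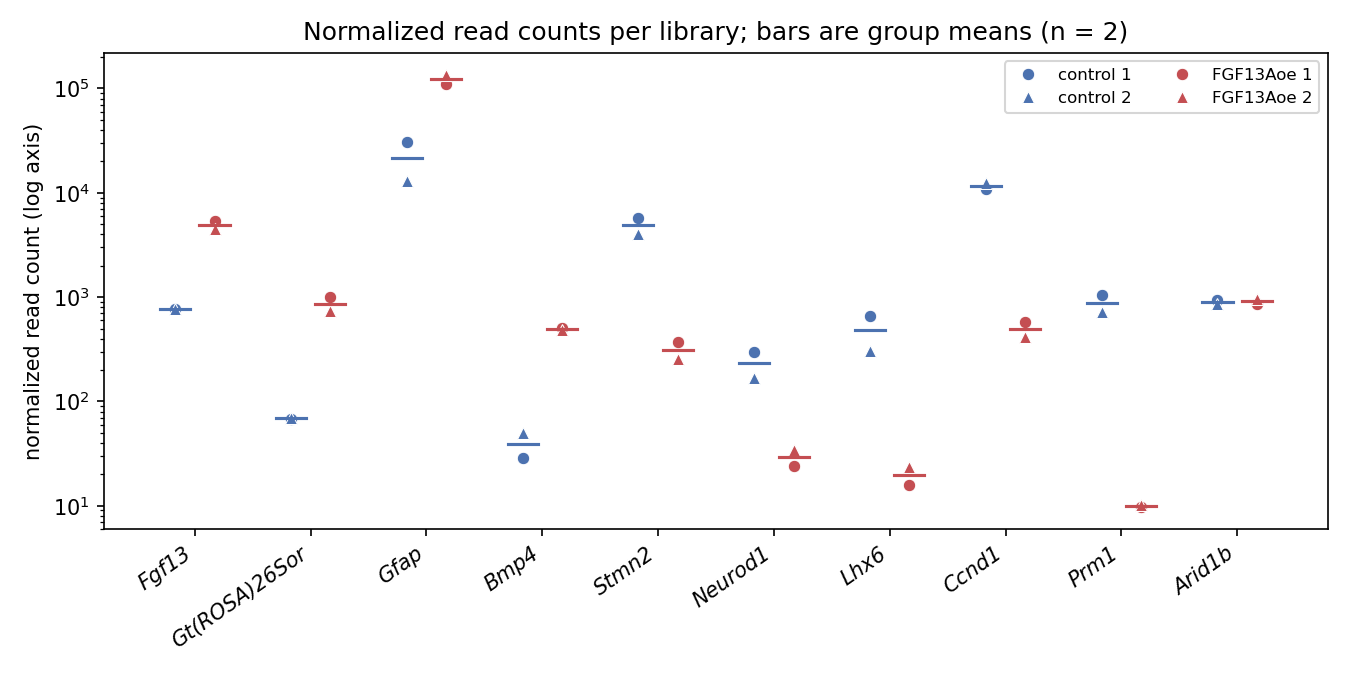
Normalized read counts (log axis) of 10 genes in each of the 4 libraries, with circles for replicate 1, triangles for replicate 2 and bars for group means. Fgf13 and Gfap are higher in both FGF13Aoe libraries, Prm1 and Neurod1 lower in both, and Arid1b overlaps between groups.

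Of 40 gene lists fixed before the data were examined, 38 had at least 5 members tested, and 23 passed the threshold in camera with a preset correlation of 0.01, 8 higher and 15 lower in FGF13Aoe. None of the 23 passed with an estimated correlation, where adjusted p ran from 0.57 to 0.9876 over the 38 lists. In the simulation that test gave p = 0.00684 for a list shifted 2-fold, against 4.3e-27 with camera at the preset correlation. That was a single simulated list of independently drawn genes, so the power of the test with 2 libraries per group was not measured. By fry, which tests whether a list's own genes move in a direction and does not compare them with other genes, 13 lists passed, 11 of them among the 23.

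Neuronal lists fell. Of 22 neuron genes tested 17 fell and 0 rose (1 rose and 17 fell adjusted over the list alone), with a median log2 change of -2.52 (camera adjusted p = 1.645e-07; adjusted p = 0.57 with an estimated correlation). The synaptic vesicle calcium sensor Syt1 fell by 3.94 on the log2 scale, the vesicle fusion protein gene Snap25 by 3.02, the growth cone gene Gap43 by 2.58. Of 31 synapse genes 24 fell and 1 rose, Nlgn2 (3 rose and 24 fell adjusted over the list alone), with a median of -1.40 (adjusted p = 1.645e-07; adjusted p = 0.57 with an estimated correlation). Syt4 and the scaffold gene Shank1 fell by 3.73 and 3.60. Of 16 GABAergic interneuron genes 10 fell and 1 rose (1 rose and 12 fell adjusted over the list alone), with a median of -1.997 (adjusted p = 0.0001052; adjusted p = 0.57 with an estimated correlation). Log2 changes were -4.49 for the interneuron transcription factor gene Lhx6, -3.68 for the vesicular GABA transporter gene Slc32a1, -3.29 for the neuropeptide gene Sst and -2.56 for Gad2, while Dlx2 rose by 1.29. Of the exonic bases of Slc32a1 24.9% overlap a predicted gene.

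Genes of ion channels and of the cytoskeleton, with which FGF13 interacts, also fell. Of 9 voltage-gated sodium channel genes 7 fell and 0 rose (1 rose and 8 fell adjusted over the list alone), with a median of -2.20 (adjusted p = 0.0005583; adjusted p = 0.57 with an estimated correlation). Log2 changes were -2.54 for Scn2a, -2.41 for Scn2b, -2.12 for Scn3a and -1.60 for Scn3b. Of 26 potassium and calcium channel genes 18 fell and 1 rose, Kcnk2 (1 and 18 also adjusted over the list alone), with a median of -1.50 (adjusted p = 1.453e-05; adjusted p = 0.57 with an estimated correlation). Log2 changes were -2.62 for Cacna1b and -2.20 for Kcnc1. Of 32 tubulin and microtubule-associated protein genes 20 fell and 3 rose, Tubb4a, Map7 and Dclk2 (4 rose and 22 fell adjusted over the list alone), with a median of -0.96 (adjusted p = 0.0001461; adjusted p = 0.57 with an estimated correlation). Stmn2, Tubb3, Dpysl5 and Tubb2a fell by 3.97, 2.99, 2.46 and 2.30, and tubulin genes are near copies of each other, so their counts are uncertain.

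Oligodendrocyte and astrocyte lists rose. Of 20 oligodendrocyte lineage genes 14 rose and 0 fell (15 rose and 2 fell adjusted over the list alone), with a median of 2.21 (adjusted p = 0.0001461; adjusted p = 0.6048 with an estimated correlation; fry 0.0709). Bcas1 rose from 791 and 1233 to 8862 and 8657, and Cnp, an enzyme gene of myelin, rose by 2.49. The early lineage genes Olig1 (log2 change -0.87, adjusted p = 0.0601), Olig2 (-0.35, adjusted p = 0.1978), Pdgfra (0.87, adjusted p = 0.0733) and Cspg4 (0.07, adjusted p = 0.7909) did not pass and were chosen after their values were seen. Of 20 astrocyte genes 12 rose and 1 fell, Acsbg1 (13 rose and 1 fell adjusted over the list alone), with a median of 1.07 (adjusted p = 9.473e-05; adjusted p = 0.57 with an estimated correlation). The neurotensin receptor gene Ntsr2 rose by 3.81, the water channel gene Aqp4 by 1.71 and the connexin gene Gja1 by 1.05.

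Progenitor genes went both ways. Of 20 neural stem cell and radial glia genes 10 rose and 2 fell, Tnc and Nes (10 and 2 also adjusted over the list alone), with a median of 0.48 (adjusted p = 0.03881; adjusted p = 0.57 with an estimated correlation). Pax6 and Prom1 each rose by 1.85 and Msi1 by 1.14, while Tnc had a log2 change of -2.51. This list did not pass without control replicate 2 (median 0.40, adjusted p = 0.1001), without FGF13Aoe replicate 1 (0.42, adjusted p = 0.0605) or without FGF13Aoe replicate 2 (0.40, adjusted p = 0.0838). Of 20 genes of neurogenic progenitors and neuronal commitment 7 rose and 9 fell (8 and 9 adjusted over the list alone), and the list did not pass (median -0.24, adjusted p = 0.717). Log2 changes were -4.75 for Neurod6, -4.01 for Tbr1 and -3.91 for Nhlh2, while Sox4 rose by 1.36; 54.6% of its exonic bases overlap a predicted gene on the opposite strand. Of 21 Notch pathway genes 10 rose and 3 fell (12 and 4 adjusted over the list alone), with a median of 0.80 (adjusted p = 0.03881; adjusted p = 0.57 with an estimated correlation; fry 0.08096). Dll3 and Mfng rose by 2.76 and 3.09, and the ligand gene Jag1 fell by 2.31. Without control replicates 1 and 2 in turn 4 and 6 members of the Notch list rose singly (medians 0.68 and 0.51), and without FGF13Aoe replicate 2 the list did not pass (median 0.74, adjusted p = 0.0838).

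**Figure D2:**
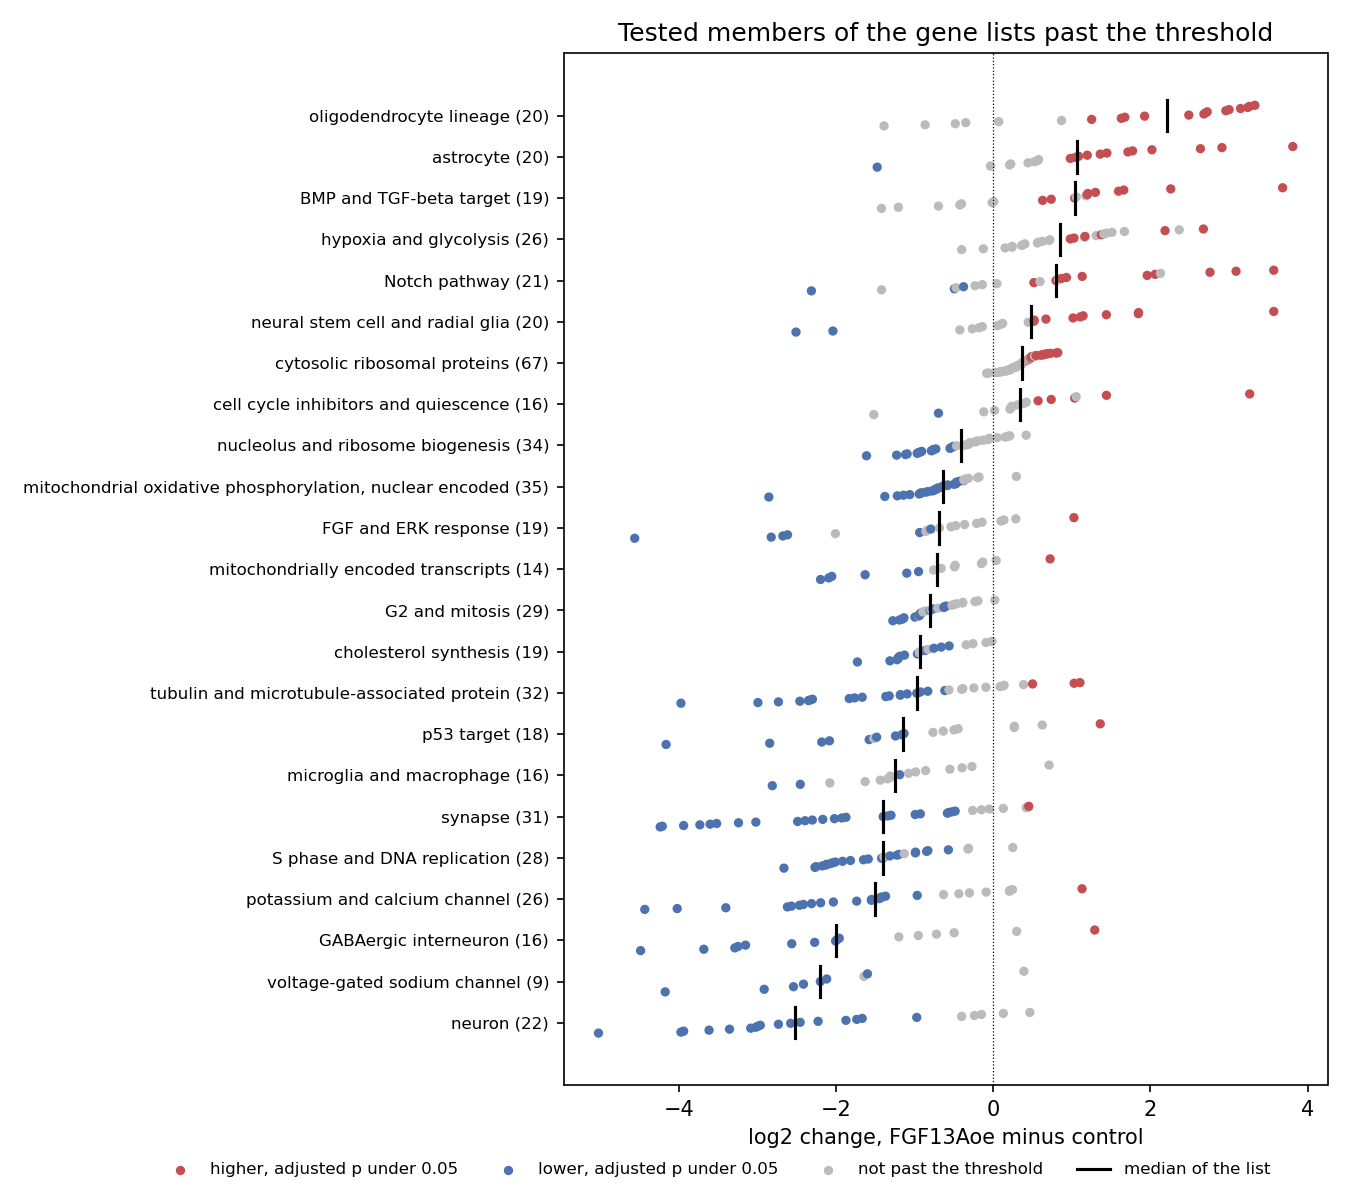
Log2 change (FGF13Aoe minus control, horizontal axis) of each tested member of the 23 gene lists past the threshold, with the number tested in parentheses; red points were higher, blue points lower and grey points did not pass, and black lines are list medians. Medians run from -2.52 for the neuron list to 2.21 for the oligodendrocyte lineage list.

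Genes of cell division fell. Of 28 S phase and DNA replication genes 23 fell and 0 rose (0 rose and 24 fell adjusted over the list alone), with a median of -1.41 (adjusted p = 1.364e-07; adjusted p = 0.6009 with an estimated correlation; fry 0.06001). Rrm2, a subunit of ribonucleotide reductase, fell by 2.25, and the replicative helicase genes Mcm2, Mcm3 and Mcm4 by 2.07, 2.04 and 1.65. Of 29 G2 and mitosis genes 16 fell and 0 rose (0 and 21 adjusted over the list alone), with a median of -0.80 (adjusted p = 9.54e-05; adjusted p = 0.6754 with an estimated correlation; fry 0.201). Cdk1 and Aurka fell by 1.14 and 1.16. Without control replicate 2, 0 members of the G2 and mitosis list passed singly, and the list passed with a median of -0.58 (adjusted p = 0.002369). Of 16 cell cycle inhibitor and quiescence genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.03881; adjusted p = 0.57 with an estimated correlation). The inhibitor genes Cdkn1c and Cdkn1b rose by 3.26 and 1.44; 30.7% of the exonic bases of Cdkn1c overlap a predicted gene. Without either control library 2 members rose singly (medians 0.33 and 0.42), and the list did not pass without FGF13Aoe replicate 1 (median 0.16, adjusted p = 0.1521). Of 18 p53 target genes 9 fell and 1 rose, Sesn1 (2 rose and 10 fell adjusted over the list alone), with a median of -1.15 (adjusted p = 0.009101; adjusted p = 0.6217 with an estimated correlation; fry 0.09126). Without either control library 4 members of the p53 list fell singly (medians -1.11 and -1.17). Plk2 and Gtse1, which act in the cell cycle, fell by 2.18 and 2.08, and Sesn1 rose by 1.36.

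Of 19 FGF and ERK response genes 6 fell and 1 rose, Il17rd (1 and 6 also adjusted over the list alone), with a median of -0.68 (adjusted p = 0.03881; adjusted p = 0.6754 with an estimated correlation; fry 0.1591). Ccnd1, which encodes cyclin D1 (chromosome 7, 144929931 to 144939925), fell from 10861 and 12426 to 581 and 415 (log2 change -4.56 ± 0.19, adjusted p = 0.00111); 23.4% of its exonic bases overlap LTO1 on the opposite strand. The feedback inhibitor genes Dusp6, Spry1 and Spry4 fell by 2.82, 2.68 and 2.62, and 24.4% of the exonic bases of Spry1 overlap a predicted gene. The list did not pass without control replicate 2 (median -0.60, adjusted p = 0.0642) or without FGF13Aoe replicate 2 (-0.40, adjusted p = 0.1918). Of 19 BMP and TGF-beta target genes 10 rose and 0 fell (11 rose and 1 fell adjusted over the list alone), with a median of 1.04 (adjusted p = 0.014; adjusted p = 0.6009 with an estimated correlation; fry 0.08096). The ligand gene Bmp4 rose from 28.7 and 49.6 to 506 and 488 (3.68 ± 0.30, adjusted p = 0.00154), and Atoh8, Id3 and Id2 rose by 2.26, 1.20 and 0.74. Without control replicates 1 and 2 in turn 3 and 4 members rose singly (medians 0.83 and 0.72), and without FGF13Aoe replicate 1 that list did not pass (median 0.74, adjusted p = 0.0785). Of 13 FGF family and receptor genes 5 rose and 5 fell (5 and 5 also adjusted over the list alone), and the list did not pass (median 0.33, mean -0.16, adjusted p = 0.9622). Apart from Fgf13, Fgfr3 rose by 1.09, and Fgf1 and Fgf12 fell by 2.58 and 1.63.

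Lists of metabolism and protein synthesis differed as well. Of 35 nuclear genes of oxidative phosphorylation 28 fell and 0 rose (0 and 32 adjusted over the list alone), with a median of -0.65 (adjusted p = 1.645e-07; adjusted p = 0.57 with an estimated correlation). The cytochrome c gene Cycs fell by 2.85, Uqcrq by 1.38 and Cox5a by 1.22. Without control replicates 1 and 2 in turn 4 and 5 members fell singly, and the list passed with medians of -0.63 and -0.66. Of 14 mitochondrially encoded transcripts 6 fell and 1 rose, mt-Rnr1 (1 and 8 adjusted over the list alone), with a median of -0.71 (adjusted p = 0.01932; adjusted p = 0.6754 with an estimated correlation; fry 0.1393). Without either control library 0 members passed singly, and the list passed with medians of -0.62 and -0.80. Transcripts of the mitochondrial genome took 3.19% and 3.23% of normalized counts in the control libraries and 1.83% and 2.65% in the FGF13Aoe libraries. Without members under 50 normalized counts that list did not pass (median -0.58, adjusted p = 0.0575), nor did it on reads without control replicate 1 by edgeR (-0.58, adjusted p = 0.1697) or DESeq2 (-0.58, adjusted p = 0.08974). Of 19 cholesterol synthesis genes 12 fell and 0 rose (0 and 15 adjusted over the list alone), with a median of -0.93 (adjusted p = 0.0002139; adjusted p = 0.6754 with an estimated correlation; fry 0.1244). Sqle, an enzyme gene of the pathway, fell by 1.22 and Msmo1 fell by 1.20. Without control replicates 1 and 2 in turn 1 and 4 members fell singly, with list medians of -0.78 and -0.97. Of 34 nucleolus and ribosome biogenesis genes 16 fell and 0 rose (0 and 18 adjusted over the list alone), with a median of -0.42 (adjusted p = 0.0005057; adjusted p = 0.57 with an estimated correlation). Rrp12, Utp20 and Ddx21 fell by 1.61, 1.23 and 1.12. The 16 falls became 4 without control replicate 1 and 3 without control replicate 2, with list medians of -0.44 and -0.37. Of 67 cytosolic ribosomal protein genes, which have many pseudogene copies, 17 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.36 (adjusted p = 1.919e-06; adjusted p = 0.6754 with an estimated correlation; fry 0.1411). Rps27 and Rpl28 rose by 0.82 and 0.69. Without control replicate 1 or 2 the list passed with medians of 0.35 and 0.41 (adjusted p = 0.0002069 and 1.522e-05), while 0 members passed singly.

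Some list calls depended on single libraries. Of 26 hypoxia and glycolysis genes 6 rose and 0 fell (1 and 0 adjusted over the list alone), with a median of 0.85 (adjusted p = 0.009101; adjusted p = 0.7581 with an estimated correlation; fry 0.4267). The list median relative to the control mean was 1.51 in FGF13Aoe replicate 1 and 0.08 in FGF13Aoe replicate 2, and without FGF13Aoe replicate 1 the list did not pass (adjusted p = 0.4262). Without either control library 0 members passed singly, with list medians of 0.74 and 0.89. The mitophagy receptor gene Bnip3l had counts of 1259 and 1245 in control and 2917 and 2236 in FGF13Aoe (log2 change 1.03 ± 0.16, adjusted p = 0.00685), and the aldolase gene Aldoc 6611 and 4580 against 9906 and 11909 (0.98 ± 0.22, adjusted p = 0.0207). Without control replicates 1 and 2 in turn adjusted p was 0.05864 and 0.05443 for Bnip3l (log2 changes 1.04 and 1.02) and 0.05285 and 0.1604 for Aldoc (1.25 and 0.72). Vegfa, the growth factor gene of blood vessels, had counts of 1144 and 1861 in control and 21240 and 4088 in FGF13Aoe (2.67 ± 0.74, adjusted p = 0.0379), and the glucose transporter gene Slc2a1 had 588 and 973 against 8809 and 658 (1.67 ± 1.13, adjusted p = 0.285); Vegfa and Slc2a1 were chosen after their values were seen. Of 16 microglia and macrophage genes 3 fell and 0 rose, C1qa, Csf1r and Trem2 (0 and 0 adjusted over the list alone), with a median of -1.25 (adjusted p = 0.0211; adjusted p = 0.6754 with an estimated correlation; fry 0.201). C1qa counts were 131 and 38.2 in control against 12.1 and 12.2 in FGF13Aoe. The microglia list did not pass without control replicate 1 (median -0.64, adjusted p = 0.0657) or without FGF13Aoe replicate 1 (-0.71, adjusted p = 0.1256), and with a minimum of 50 normalized counts it had a median of -0.40 (adjusted p = 0.9978). On reads without control replicate 1 its median was -0.46 by edgeR (adjusted p = 0.4538) and -0.49 by DESeq2 (adjusted p = 0.6036). The sex-linked Ddx3y, encoded on the Y chromosome, had counts of 4.95 and 146 in control and 0 and 0 in FGF13Aoe, and Xist, expressed from the inactive X chromosome, had 18658 and 12206 against 30159 and 31301.

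**Figure D3:**
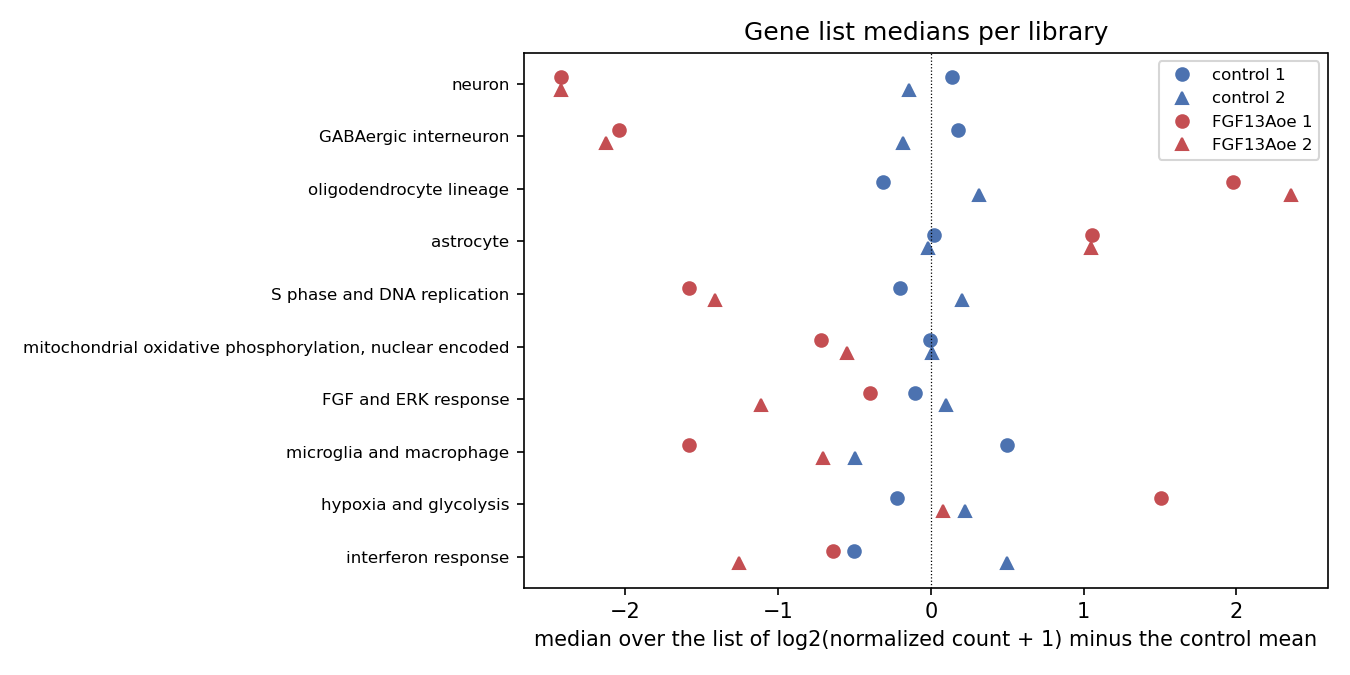
Median over the tested members of 10 gene lists (vertical axis) of log2(normalized count + 1) minus the control mean (horizontal axis) in each library, with circles for replicate 1 and triangles for replicate 2. FGF13Aoe replicates lie together for the neuron list (-2.42 and -2.42) and apart for hypoxia and glycolysis (1.51 and 0.08).

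The other 13 tested lists did not pass. Adjusted p was 0.05437 for choroid plexus and ependyma (median -1.30), 0.05477 for interferon response (-1.03), 0.1504 for endothelial cells and pericytes (-1.08), 0.1778 for Hedgehog targets (0.49) and 0.3293 for fibroblasts and meningeal cells (-0.48). It was 0.4194 for Wnt targets (-0.39), 0.4502 for extracellular matrix and adhesion (0.05), 0.5899 for dorsal telencephalon and hippocampus identity (-0.49), 0.6832 for antigen presentation (0.26) and 0.717 for ventral telencephalon identity (-0.26). It was 0.7797 for the unfolded protein and integrated stress response (0.01), and 0.967 for both the BAF complex (median 0.02, mean -0.19) and immediate early genes (median -0.06, mean 0.05). The mean of the extracellular matrix list was -0.48, against a median of 0.05. In the BAF list 6 genes rose and 6 fell, and the 4 with the smallest p were Actl6b (log2 change -2.72), Dpf3 (-2.07), Bcl11b (-2.05) and Bcl11a (-1.47), which are used in neurons. In the extracellular matrix list Tnr rose by 2.81, and Hapln1 and Lamb1 fell by 4.87 and 3.19. Interferon genes Ifi27, Rtp4, Isg15 and Usp18 fell by 1.43, 1.33, 1.96 and 1.59, and their counts were highest in control replicate 2 (674, 152, 139 and 149). Without that library (control replicate 2) their log2 changes were -1.13, -0.93, -1.28 and -0.996 (adjusted p = 0.05075, 0.1933, 0.1727 and 0.2431), and the interferon response median was -0.29 (adjusted p = 0.3647). No erythroid gene reached the minimum, so that list had 0 genes tested, and the sex-linked list had 1, Xist.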

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

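Fgf13 stayed higher in FGF13Aoe under all alternatives, with log2 changes of 2.53 to 2.81. The direction of all 5373 called genes was kept under all alternatives in which they had a value. Where a gene's groups do not overlap, leaving out a library cannot reverse it, so for such genes this was fixed in advance. Counts moved by over 1.5 times only where a control library was left out, which leaves a lone control assumed to vary like the FGF13Aoe libraries. Over the 4 libraries left out in turn, 551 to 2822 genes were higher and 867 to 3447 lower, the lowest without control replicate 1 and the highest without FGF13Aoe replicate 2. Of the 5373 calls, 1402 were shared without control replicate 1, 1709 without control replicate 2, 4502 without FGF13Aoe replicate 1 and 4820 without FGF13Aoe replicate 2. Of named genes, 58 lost their call without control replicate 1 and 54 without control replicate 2, against 8 and 9 without FGF13Aoe replicates 1 and 2. On the reads of 3 libraries, without control replicate 1, edgeR called 537 higher and 1086 lower and DESeq2 called 732 and 975; these 2 tests were chosen after seeing the data. The planned count tests on all 4 libraries were withdrawn after they had been run and seen, because the step of that library is too near 1, and count as not run. With the replicate number as a block 2049 genes were higher and 2647 lower, 24 lists passed and Fgf13 stayed at 2.67; the numbers are not stated to pair samples, and deviations of same-numbered libraries from their group means correlated at -0.103 across genes. Of the 38 lists 0 passed with an estimated correlation and 13 passed by fry, 11 of them among the 23. The power of the first of these tests with 2 libraries per group was not measured, and a failure in it does not show that a list was unchanged. In the astrocyte and the neural stem cell lists the estimated correlations, 0.00878 and 0.00756, were below the preset 0.01. Unadjusted camera p still rose, from 1.745e-05 to 0.04923 and from 0.02277 to 0.1458. A higher correlation between genes therefore does not account for the loss of these calls. For the other lists the cause of the difference between the tests was not tested. Without each library in turn 18 to 24 lists passed.

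A list's direction is the sign of its median, a definition chosen after seeing the data. Values that changed sign belonged to lists and a gene that did not pass in the main test. Over the libraries left out, the Arid1b log2 change ran from -0.0651 (without FGF13Aoe replicate 2; -0.0535 without control replicate 2) to 0.0827. Without a filter the median was 0.0837 for neurogenic commitment and -0.29 for the FGF family; from the authors' values these were 0.0718 and -0.0842. With a minimum of 50 it was 0.45 for endothelial cells, 0.12 for dorsal telencephalon and 0.11 for immediate early genes, fewer genes being tested. With median centring it was 0.00807 for immediate early genes. Without control replicate 1 it was -0.0421 for the unfolded protein response and -0.0121 for antigen presentation, and by edgeR and DESeq2 0.0112 and 0.00992 for Wnt targets. Without FGF13Aoe replicate 1 it was -0.17 for the unfolded protein response, -0.0749 for antigen presentation and -0.11 for extracellular matrix. Without FGF13Aoe replicate 2 it was -0.0760 for the BAF complex and 0.22 for immediate early genes. The opposite ends of these ranges were 0.51 for the unfolded protein response (without FGF13Aoe replicate 2, where it passed), 0.28 for antigen presentation, -0.54 for immediate early genes, 0.0567 for extracellular matrix and 0.12 for the BAF complex. Lists that did not pass in the main test passed in some alternatives, all in the same direction. Without a filter adjusted p was 0.005726 for endothelial cells, 0.01252 for choroid plexus, 0.02768 for interferon response and 0.03151 for fibroblasts, and with a minimum of 50 it was 0.03947 for Hedgehog targets. With TMM it was 0.04994 for choroid plexus and interferon response, and with median centring 0.0415 and 0.03703. With the replicate number as a block it was 0.04567 for choroid plexus, and from the authors' values 0.02946 for endothelial cells and 0.009048 for interferon response. By fry it was 0.02283 for choroid plexus and 0.03608 for Hedgehog targets. Endothelial cells, choroid plexus and dorsal telencephalon passed without control replicate 2 (0.02141, 0.01297 and 0.02396). Interferon response passed without control replicate 1 by limma, edgeR and DESeq2 (6.955e-05, 0.0001193 and 0.0001088). Apart from the smaller gene sets the cause was not tested.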

Other observations

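The tests in this part were chosen after the results were seen, apart from the tests of the lists fixed beforehand and of leaving out each library, which were planned. Gene families, taken as symbols with the same letters before the first digit and at least 10 tested members, gave 160 families, of which 18 passed in camera and 0 with an estimated correlation (adjusted p at least 0.928). Zinc finger genes named Zfp formed the largest, with 84 of 355 higher and 9 lower (median log2 change 0.39, adjusted p = 2.11e-05; adjusted p = 0.928 with an estimated correlation). Histone demethylase genes named Kdm were higher in 9 of 17 and lower in 0, and Sox transcription factor genes higher in 9 of 16 and lower in 1. Calcium channel genes named Cacna were lower in 10 of 11, synaptotagmin genes in 8 of 15, inward rectifier genes named Kcnj in 7 of 11, cadherin genes named Cdh in 6 of 16 and proteasome genes named Psmd in 8 of 14. Most mitochondrial ribosomal protein genes did not pass singly: 7 of 29 were lower and 0 higher in the small subunit, and 12 of 48 lower and 1 higher in the large subunit, against 2906 lower of all 15204 tested genes.

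Counts by transcript class were not tested for enrichment. Of 321 lincRNA genes tested 85 were higher and 33 lower (median log2 change 0.59), and of 318 antisense genes 71 and 16 (0.75), against 2172 higher and 2803 lower of 13552 protein-coding genes (-0.05). Of 311 processed pseudogenes 7 were higher and 8 lower (0.04). Near Gt(ROSA)26Sor, 3 of 34 tested genes within 1 Mb were higher and 8 lower (median -0.18). Setd5, which starts next to Gt(ROSA)26Sor, was higher, with a log2 change of 1.11 ± 0.25 (adjusted p = 0.0221). Called genes made up 36.15% of X-linked and 35.32% of autosomal genes (Fisher's exact test, two-sided, p = 0.709). By direction, 12.88% of X-linked and 16.36% of autosomal genes were higher (Fisher's exact test, two-sided, p = 0.0342), and 23.27% and 18.96% were lower (Fisher's exact test, two-sided, p = 0.017); genes are not independent of each other. Reads of Ddx3y numbered 5, 180, 0 and 0 in control replicates 1 and 2 and FGF13Aoe replicates 1 and 2, while Xist had 15004 reads in control replicate 2, the library with most Ddx3y reads.

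Prm1 reads in the control libraries were not expected in a hippocampal culture. Germ cell RNA is argued against, since 8 other germ cell transcripts together held 3 reads against 1938 of Prm1, a ratio of 0.001548. Some Cre transgenes end in protamine 1 sequence, so the reads may come from a transgene. One that follows endogenous Gfap is argued against, because the log2 change of Prm1 minus that of Gfap was -8.953 (SE 0.523). The human GFAP promoter of hGFAPCre is active in neural progenitors too and need not follow endogenous Gfap. That value therefore leaves hGFAPCre open as the source. A lack of Cre recombination in the FGF13Aoe cells is argued against as well, since the lower of the Fgf13 and Gt(ROSA)26Sor log2 changes was 2.669 (SE 0.136). A transgene that control cells carry or use and FGF13Aoe cells do not stays open and was not tested, and it would be a difference between the groups besides FGF13A.

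The neuron list was lower and the astrocyte and oligodendrocyte lists higher in FGF13Aoe. These calls were lost in camera with an estimated correlation (adjusted p = 0.57, 0.57 and 0.6048), a test whose power with 2 libraries per group was not measured. Unequal sex of the cells as the whole cause is argued against, since the neuron list median was -2.579 without control replicate 2, against -2.517 with all libraries. A lower share of neurons alone would raise markers of other cell types alike. Oligodendrocyte and astrocyte medians, over members with at least 50 counts in 2 libraries, differed by 1.443. The 95% bootstrap interval, 0.184 to 2.16, lay above 0 but was wide, and it resampled list genes, not libraries. Microglia, endothelial and choroid plexus medians were -1.25, -1.08 and -1.30, or -0.40, 0.45 and -1.29 with a minimum of 50 counts. These lists did not rise with the other 2, but they hold genes with low counts, so this explanation stays open. A test with low microglia genes, which argued against it, was replaced after its value was seen. Weaker growth factor signalling in the FGF13Aoe cultures would lower the FGF and ERK response list, and its median was -0.684 (95% bootstrap interval -0.935 to -0.211). That interval resampled list genes and leaves out the spread between libraries. Relative to the control mean the median was -0.40 in FGF13Aoe replicate 1 and -1.11 in FGF13Aoe replicate 2. The list's call was lost without control replicate 2, without FGF13Aoe replicate 2 and in camera with an estimated correlation (adjusted p = 0.6754). This explanation stays open. An effect of FGF13A itself and a difference between litters or cultures stay open, untested.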
